A study of Oncorhynchus mykiss with 22 samples.

How the data were processed

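Gene expression was measured with 1-colour (Cy3) oligonucleotide arrays in pooled RNA of whole rainbow trout larvae at 1 day post hatch. Per the labels' protocols, each array received 600 ng of labelled cRNA, amplified from 150 ng of RNA. The series text describes eggs of 2 females that were pooled and fertilised with sperm of 4 males, pools of 10 larvae per treatment, and 1 replicate per male. Each of the 22 samples is 1 array. Samples were grouped by the kind of sperm and the zygotic treatment in their titles, and the replicate number is the number of the male. The group that combines EY sperm with 3AB holds males 1 and 2; arrays of males 3 and 4 in that group were not analysed here.

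The intensity values come from the authors' scanner files, which Agilent Feature Extraction 10.7.3.1 made, per the file headers: the processed signal of each spot is background-subtracted and detrended and is not normalised between arrays, with low values replaced by a surrogate. The other deposited columns used are the mean and local background intensity of each spot and flags of 0 or 1, also from the file headers' protocol. A text of the authors on data processing was not given in the sources used here. The deposited log2 values in the series matrix were compared with the same arrays' processed signals. On each array, 100% of the probes differed from log2 of the processed signal by the same shift within 0.01, and the median of each column of the matrix was 7.53, so that the matrix holds log2 processed signals centred on a common median. The scale and centring of the matrix are thus known, and a 1-colour value has no direction.

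Each array holds 61657 spots other than controls, which belong to 60195 probes, 1462 of them with 2 spots. Control spots and spots marked as outliers in the files were left out, and spots of 1 probe were averaged on the log2 scale. No spot was saturated. Values are log2 of the processed signal minus the 75th percentile of its array. A probe was tested if the files mark it as well above background on at least 4 of the 22 arrays, which left 52080 probes, with 582 missing values among them. The number of arrays limits the precision.

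Differences were tested per probe with limma 3.58.1 in R 4.3.3 with the package data.table at version 1.17.8 (lmFit and eBayes, two-sided moderated tests), in 1 fit of 6 group means over the 22 arrays, which share 1 estimate of the spread because the group of EY sperm with 3AB has 2 arrays. Differences between males were tested with limma's moderated F-test on the male terms of a fit with group and male. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe was called at an adjusted p below 0.05. The replicates are separate crosses with a different male on the same pool of eggs, so the p-values measure the spread between males together with that of the assay. Male is not balanced in EY with 3AB, which holds males 1 and 2 only. Without a male block, comparisons that use this group, the averaged one included, also carry part of the difference between males 1 and 2 and males 3 and 4. The fit with male as a block takes that part out.

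The design, the tests and the alternatives were fixed before the data were examined. The alternatives were the male as a block, normexp background correction (offset 50) of the mean signal with its median local background, quantile normalisation, no filter, a filter for probes well above background on all 22 arrays, a fit of only the groups compared, the slide as a block, the values of the series matrix, and leaving out each array in turn. After the data had been seen, 2 fits were added: the log2 75th percentile of each array (array brightness) as a covariate, and male and slide together as blocks. Slide and scan are identical in the files: the arrays lie on 3 slides, each read in its own scan.

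The same number marks the same male in every group, so the numbers pair the samples by the series text. Deviations from the group means correlated between arrays of the same male at a mean r of 0.171 (15 pairs of arrays) for male 1, 0.0355 (15 pairs) for male 2, 0.299 (10 pairs) for male 3 and 0.206 (10 pairs) for male 4, over probes, which are not independent, against -0.0528 for 150 pairs of arrays of different males and groups. No arrays were near-copies: the highest correlation between 2 arrays was 0.995 and the lowest 0.970.

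The files pair almost no probes with a gene. Of the 60195 probes, 64 carried a name that could be read as a gene, 4 of these through RefSeq accessions (4 of 7 matched) in the table of the assembly USDA_OmykA_1.1; 59 of the 64 were tested. Many of these names are cut off in the files (for example trout, fatty or ATP-citrate) and are printed as given. Single genes were chosen by a rule fixed before the data were examined: per comparison, the called probes with a gene name that changed in the same direction in every pair of arrays of the same male (8 of 10 pairs in the averaged comparison), at most 10 in each direction; where fewer than 5 such genes existed, the 5 named genes with the smallest p; CYP1A and 5 DNA damage genes where measured, of which cyp1a3 alone was found; and up to 4 members of each gene list. For males it took the 10 named genes with the smallest p. The 4 unnamed probes printed were chosen after their values were seen: among called probes with the same direction in at least 8 of 10 pairs and well above background on at least 1 array of every group, the 2 with the largest rise and the 1 with the largest fall in the averaged comparison, and the 1 probe that was well above background on every untreated array and on no array of F or EY sperm with 3AB. Where a probe was not well above background on any array of a group, or of its part on a slide, the difference is given as a lower bound: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value of a probe well above background.

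Of 27 gene lists fixed beforehand, 2 had at least 5 measured genes and were tested, with 4 groups built afterwards from the array's own gene names before any comparison was seen. They were tested with limma's camera (preset correlation 0.01, 1 probe per gene, missing values set to the group mean), repeated with an estimated correlation, and with fry, and adjusted over the 6 lists of a comparison. The other 25 fixed lists, such as base excision repair, had fewer than 5 measured genes and were not tested, nor was a group of 4 muscle fibre proteins. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

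The fits were tested on simulated data with the spread of the 52080 probes, in which 200 probes were changed. The simulated noise was independent between probes and arrays, with no differences between males, slides or array brightness. The shares recovered and the false calls thus check the fit itself and do not describe arrays that hold such differences. In the simulated comparison of 3AB in F, 28.4% of the 67 probes changed 1.5-fold, 62.7% of the 67 changed 2-fold and 92.4% of the 66 changed 4-fold were recovered, with 6 false calls. For 3AB averaged over sperm the shares were 65.7%, 80.6% and 100%, with 8 false calls. For LDL against F without 3AB they were 25.4%, 61.2% and 90.9%, with 10 false calls.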

Results

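Whole rainbow trout larvae were profiled at 1 day post hatch in a crossed design of 3 kinds of sperm and 2 zygotic treatments. The sperm was fresh (F) or had been cryopreserved by either of 2 procedures, which the labels call LDL and EY. After fertilisation, part of the eggs was treated with 3-aminobenzamide (3AB), an inhibitor of poly(ADP-ribose) polymerase (PARP), to block base excision repair in the zygote. The series text places the start of 3AB at 10 min after fertilisation and the treatment label at 5 h. There were 4 arrays, each of a different male, for F without 3AB, F with 3AB, LDL without 3AB, LDL with 3AB and EY without 3AB, and 2 arrays for EY with 3AB, 22 in all. The 75th percentile of the processed signal ranged from 515 to 1394 between arrays, and between 44459 and 52257 of the 60195 probes were well above background.

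The arrays lay on 3 slides that did not divide the groups evenly. Slide 1 held 1 array with 3AB and 6 without, slide 2 held 3 with and 4 without, and slide 3 held 6 with and 2 without. Of the 4 arrays of F with 3AB, 3 were on slide 3, where 1 array of F without 3AB lay, and LDL without 3AB had 3 arrays on slide 1 and none on slide 3. The first principal component over the tested probes held 21.5% of the variance and followed array brightness, the log2 of the 75th percentile, with Pearson's r = -0.917 and Spearman's rho = -0.885 over the 22 arrays (permutation p = 1e-05 each, the smallest that 100000 permutations can give; 1 relation tested). Without the 2 arrays farthest from the median brightness, r was -0.880. Within slides 1, 2 and 3, with 7, 7 and 8 arrays, r was -0.986, -0.900 and -0.833. Brightness was lowest for male 3, at a mean log2 of 9.30 ± 0.22 (SD, n = 5), and highest for male 1, at 10.23 ± 0.14 (SD, n = 6).

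**Figure D1:**
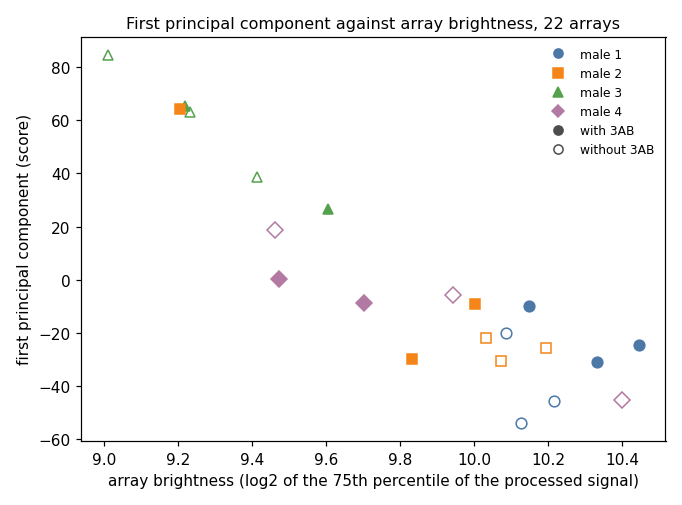
Score on the first principal component of the tested probes against array brightness (log2 of the 75th percentile of the processed signal) for the 22 arrays; colour and symbol give the male and filled symbols are arrays with 3AB. The score falls as brightness rises (r = -0.917).

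The treatment with 3AB was compared with no 3AB within each kind of sperm, which asks what this treatment, meant to inhibit zygotic repair, changed in the larvae. Whether repair was inhibited was not measured on the arrays. In F, 12 of 52080 probes were called, 3 higher and 9 lower with 3AB. In LDL, 19 were called, 4 higher and 15 lower. In EY, 9 were called, 4 higher and 5 lower, a balance that depended on the processing: with normexp background 9 were called, 1 higher and 8 lower, and with only probes well above background on all 22 arrays 10, 1 higher and 9 lower, each list sharing 5 with the 9. Each called probe changed in the same direction in every pair of arrays of the same male (4, 4 and 2 pairs). These pairs are the arrays that made the calls, so such agreement is largely fixed by the calling. EY with 3AB holds males 1 and 2 only, so without a male block its comparison carries part of the difference between males 1 and 2 and males 3 and 4. For that difference 5376 probes were called. With male as a block the counts were 21 in F, 38 in LDL and 15 in EY, the last including 8 of the 9. With slide as a block they were 6, 1 and 4, all of them among the probes called without it. Under the slide block the called probes kept their directions, and their median absolute log2 difference was 1.26 in F, 1.60 in LDL and 2.23 in EY, against 1.28, 1.63 and 2.19 without it, while the median standard error rose from 0.18 to 0.20 in F, from 0.18 to 0.24 in LDL and from 0.22 to 0.23 in EY. Fits of only the groups compared called 3 in F, 2 in LDL and 2 in EY, of which 2, 1 and 2 were among those above. Male and slide together as blocks called 1, 1 and 12, and normexp background 7 in F and 9 in LDL. The counts also depended on single arrays. In F, the count fell to 7 without the untreated array of male 2, 6 without that of male 4 and 6 without the 3AB array of male 3. In LDL it fell to 10, 7 and 4 without the untreated arrays of males 1, 2 and 3, and to 5, 3 and 5 without the 3AB arrays of males 1, 3 and 4. In EY it fell to 5, 4 and 5 without the untreated arrays of males 2, 3 and 4, and rose to 32 or 60 when leaving out male 1 or male 2 left a single array with 3AB, assumed to vary like the other groups.

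The 3 kinds of sperm shared called probes. Of the probes called for 3AB, 7 were common to F and LDL, 5 to F and EY and 6 to LDL and EY, where independent lists of these lengths would share 0.00438, 0.00207 and 0.00328 probes, and 3 probes were called in all 3. The lists are not independent, because the 3 comparisons share 1 estimate of each probe's spread. The numbers for independent lists are therefore too low a measure of chance. Every probe called in 1 kind of sperm changed in the same direction in both others (12 of 12 from F, 19 of 19 from LDL and 9 of 9 from EY). Over all tested probes, which are not independent replicates, the log2 differences correlated at r = 0.312 between F and LDL, 0.263 between F and EY and 0.0948 between LDL and EY. Under the slide block these were 0.231, 0.234 and 0.0537.

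Averaged over the 3 kinds of sperm, 361 probes were called for 3AB, 159 higher and 202 lower, and 214 with normexp background, 206 of them among the 361. Their median absolute log2 difference was 0.67, and 95 differed by more than 1 on the log2 scale. All 361 had the same direction in each of the 3 kinds of sperm, 358 had it in at least 8 of the 10 pairs of arrays of the same male, and 236 had it in all 10. The calls were made on the mean of these same differences, so this agreement is largely fixed by the calling and is no replication. The 25 probes called in at least 1 kind of sperm were all among the 361. With male as a block, 799 probes were called, 391 higher and 408 lower, including 357 of the 361. With slide as a block, 126 were called, 46 higher and 80 lower, including 119 of the 361; all 361 kept their direction, their median absolute log2 difference was 0.68, and the median standard error over all probes rose from 0.113 to 0.132. Within single slides, and within kinds of sperm on them, 358 of the 361 probes kept their direction on slide 1 (EY, 1 array with 3AB against 3), 358 on slide 2 (F and LDL, 2 against 4) and 359 on slide 3 (F, 3 against 1). These counts use the same arrays that made the calls. When probes were called from the other slides only, 62 of 63 kept their direction on slide 1, 53 of 53 on slide 2 and 23 of 23 on slide 3.

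**Figure D2:**
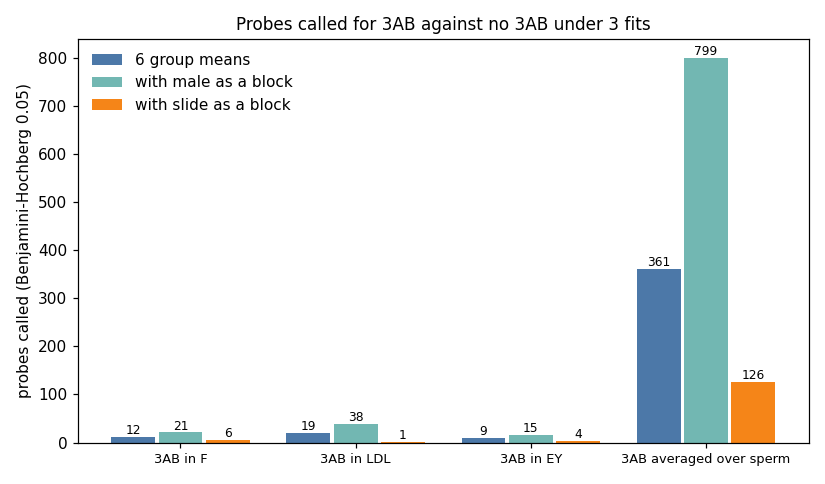
Number of probes called for 3AB against no 3AB (Benjamini-Hochberg 0.05) within F, LDL and EY sperm and averaged over them, under a fit of 6 group means, with male as a block and with slide as a block. The averaged comparison calls 361, 799 and 126 probes.

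The largest difference belonged to a single probe without a gene name, CUST_11300_PI425536763. Its value relative to the 75th percentile was 1.71 ± 0.43 (SD, n = 4) in F, 1.47 ± 0.45 (SD, n = 4) in LDL and 2.27 ± 0.54 (SD, n = 4) in EY without 3AB, where it was well above background on all 12 arrays. With 3AB it was not well above background on any of the 4 arrays of F or the 2 of EY, and in LDL it was on 1 of 4, that of male 2, at -4.11. Its signal was at least 312-fold higher without 3AB in F (limma adjusted p = 2.08e-06) and at least 654-fold higher in EY (adjusted p = 1.99e-06); in LDL its mean with 3AB was -6.98 ± 2.05 (SD, n = 4; adjusted p = 6.38e-06, but 0.0529 with male and slide together as blocks, where the log2 difference was -8.15 against -8.46 and the SE 1.03 against 0.66). It fell in 10 of 10 pairs. Where a slide held both treatments of a kind of sperm, it was well above background on every untreated array and on none with 3AB, and its signal was at least 650-fold higher without 3AB in EY on slide 1, 518-fold in F and 124-fold in LDL on slide 2, and 194-fold in F on slide 3. The next fall among probes measured in every group was that of CUST_9458_PI425536763, with a log2 difference of -2.96 (SE 0.31, adjusted p = 4.66e-05, 9 of 10 pairs), or -2.80 with slide as a block (adjusted p = 0.00182). It was well above background on all 12 untreated arrays, and with 3AB on 1 of 4 arrays of F, 1 of 4 of LDL and 2 of 2 of EY. The largest rises among called probes measured in every group were those of CUST_6770_PI425536763, at 2.28 (SE 0.34, adjusted p = 0.00195), and CUST_4911_PI425536763, at 1.77 (SE 0.18, adjusted p = 3.12e-05), both in 10 of 10 pairs. The slide block gave 2.08 (adjusted p = 0.0445) and 1.78 (adjusted p = 0.00112). Without 3AB, the former was well above background on 2 of 4 arrays of F, 4 of 4 of LDL and 2 of 4 of EY, and the latter on 3 of 4, 4 of 4 and 1 of 4. With male and slide together as blocks the former was 2.27 (adjusted p = 0.0575). These 4 probes were chosen after their values were seen. Within slides and kinds of sperm, and where it was well above background on every array compared, the log2 difference (3AB minus none) of CUST_9458_PI425536763 was -3.63 in EY on slide 1 and -1.67 in F on slide 2, that of CUST_6770_PI425536763 was 2.63 in LDL on slide 2, and that of CUST_4911_PI425536763 was 1.00 in LDL on slide 2 and 1.70 in F on slide 3. Where no array of the lower side was well above background, CUST_9458_PI425536763 was at least 4.99-fold higher without 3AB in LDL on slide 2 and 6.05-fold in F on slide 3, CUST_6770_PI425536763 at least 9.39-fold higher with 3AB in F on slide 3, and CUST_4911_PI425536763 at least 4.55-fold in EY on slide 1.

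**Figure D3:**
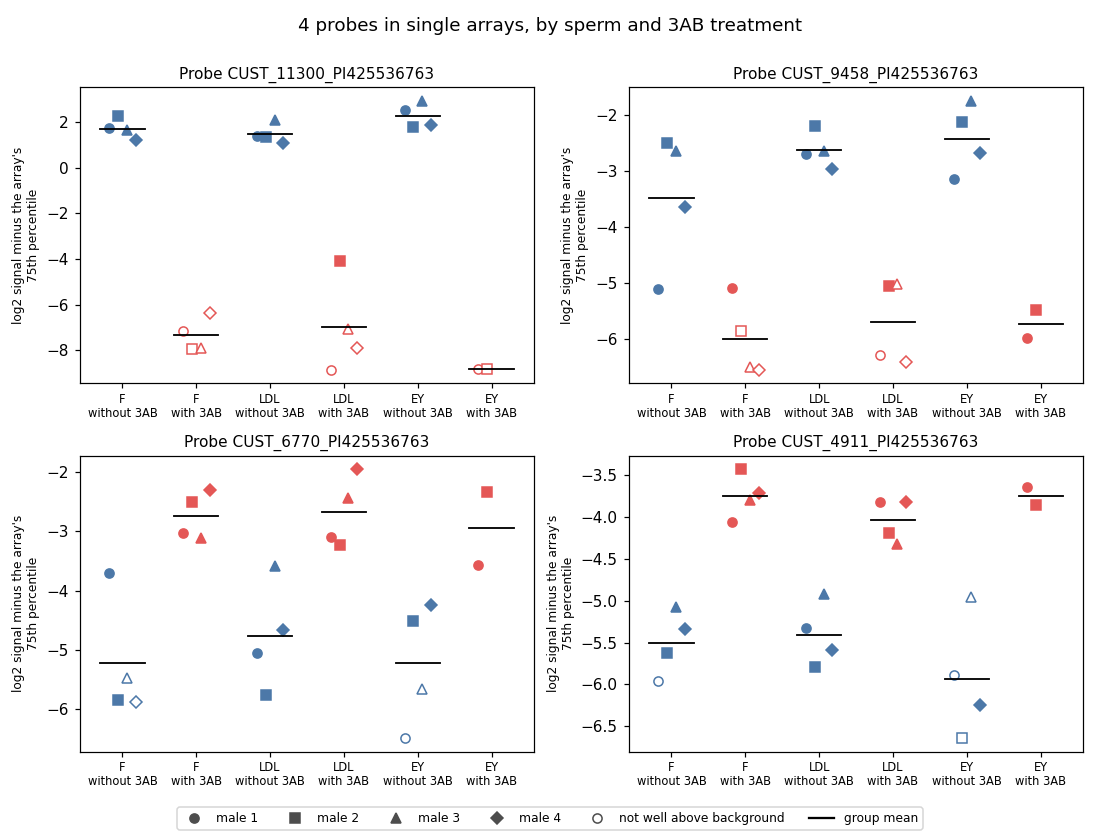
Log2 signal minus the 75th percentile of the array for 4 probes on the 22 arrays, by kind of sperm and treatment; symbols give the male, open symbols are arrays on which the probe was not well above background, and bars are group means. The values of CUST_11300_PI425536763 lie between 1.07 and 2.92 on the untreated arrays and between -8.86 and -4.11 on the arrays with 3AB.

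The files pair almost no probes with gene names, and none of the 59 tested probes with a name was called by limma for 3AB. At an unadjusted p below 0.05 there were 3 of them in F, 4 in LDL, 1 in EY and 4 averaged. With male as a block 1 passed in the averaged comparison and with slide as a block 0. The 5 named genes with the smallest p in the averaged comparison were Glut2, a probe whose name the file cuts to trout, glucose-6-phosphatase, GST and LC3B. Glut2 had a log2 difference of 0.29 (SE 0.068, adjusted p = 0.0545, 9 of 10 pairs) and trout of -0.31 (SE 0.073, adjusted p = 0.0591, 10 of 10 pairs). Glut2 passed without the untreated F array of male 1 (0.32, adjusted p = 0.0166) or the untreated LDL array of male 2 (0.31, adjusted p = 0.0408). The trout probe passed without the 3AB array of F of male 3 (-0.34, adjusted p = 0.0307) or the untreated LDL array of male 4 (-0.34, adjusted p = 0.0312). With quantile normalisation Glut2 passed at 0.0425, and with only probes well above background on all 22 arrays Glut2 passed at 0.0415 and trout at 0.0452. Glut2 rose from 0.59 ± 0.25 (SD, n = 4) to 0.91 ± 0.027 (SD, n = 4) in F, from 0.58 ± 0.17 (SD, n = 4) to 0.93 ± 0.093 (SD, n = 4) in LDL and from 0.41 ± 0.029 (SD, n = 4) to 0.63 ± 0.027 (SD, n = 2) in EY. With male as a block, trout passed at an adjusted p of 0.0173 and Glut2 did not, at 0.0559. With slide as a block neither passed, at 0.317 and 0.128. The other 3 had adjusted p-values of 0.332, 0.481 and 0.572. In F the smallest p-values were those of glucose-6-phosphatase, trout, Glut2, RARb and calpain_1, with adjusted p-values from 0.631 to 1.00. In LDL they were those of Glut2, LC3B, PPARg, trout and GST, from 0.696 to 0.881, and in EY those of ATP-citrate, phosphoenolpyruvate, trout, hexokinase and RARb, all at 0.999. The probe for cyp1a3, a cytochrome P450 gene, differed by 0.011 (SE 0.095, adjusted p = 0.999, 5 of 10 pairs) in the averaged comparison, and by -0.011 with male and -0.017 with slide as a block.

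The effect of cryopreservation was compared without 3AB. No probe was called for LDL against F, EY against F or LDL against EY by limma, and none with male or slide as a block. Of the 52080 probes, 1092, 1681 and 1151 had an unadjusted p below 0.05 (2.10%, 3.23% and 2.21%). The counts were 2475, 2784 and 2591 with male as a block, and 2113, 1005 and 1030 with slide as a block. Without a block, each share was below the 0.05 that chance gives on average. That fit leaves differences between males in its spread. The fit with male as a block takes them out, and its counts were near the share of 0.05 that chance gives, with no probe called either. The number of arrays limits the precision, so the lack of calls does not show an absence of effects. The named genes with the smallest p were PPARg, atg4b, LC3B, glucose-6-phosphatase and fbx32 for LDL against F, RARb, calpain_1, atg12l, PPARg and Glut2 for EY against F, and RARb, SOD1, phosphoenolpyruvate, calpain_1 and atg4b for LDL against EY. Of the 59 named probes, 1, 2 and 3 had an unadjusted p below 0.05, and 0 passed, at adjusted p-values of 1.00. RARb had a log2 difference of -0.89 between EY and F (SE 0.25, adjusted p = 1.00, 3 of 4 pairs). For cyp1a3 the differences were -0.10, -0.034 and -0.070 in these 3 comparisons.

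With 3AB, the kinds of sperm were compared to ask whether larvae from cryopreserved sperm differed under a treatment meant to inhibit repair. No probe was called for LDL against F, EY against F or LDL against EY by limma, and none with male or slide as a block. An unadjusted p below 0.05 was found for 340, 716 and 857 probes (0.65%, 1.37% and 1.65%), shares below the 0.05 that chance gives on average. The counts were 695, 750 and 875 with male as a block, and 387, 656 and 948 with slide as a block. Leaving out either array of EY with 3AB left a group of a single array, assumed to vary like the other groups, and 27 or 46 probes were then called for EY against F and 28 or 47 for LDL against EY, without male 1 or male 2 respectively. The named genes with the smallest p were PPARb, elov12, Wnt4b, RARa and lipoprotein for LDL against F, PPARg, Sox5, Glut2, elov12 and glucose-6-phosphatase for EY against F, and Glut2, PPARg, RARa, Sox5 and MSX1 for LDL against EY, all at adjusted p-values of 1.00. Of the 59 named probes, 0, 2 and 2 had an unadjusted p below 0.05. RARa differed by 0.75 between LDL and F, and by -0.14 without the array of male 2 of LDL with 3AB. For cyp1a3 the differences were -0.0091, -0.12 and 0.11.

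Whether the response to 3AB differed between kinds of sperm was tested as an interaction. No probe was called for LDL against F or for EY against F by limma, and none with male or slide as a block. An unadjusted p below 0.05 was found for 716 and 981 probes (1.37% and 1.88%). With male as a block there were 1953 and 1079, and with slide as a block 1356 and 542. The median standard errors were 0.256 and 0.287, against 0.113 for 3AB averaged over sperm. The lack of calls thus does not show equal responses. For EY against F, 17 or 26 probes were called when male 1 or male 2 was left out of EY with 3AB. The named genes with the smallest p were glucose-6-phosphatase, L-3-hydroxyacyl-CoA, PPARg, PPARa and LC3B for LDL against F, and RARb, Sox5, RXR, glucose transporter 1 and LOC100136786 for EY against F, at adjusted p-values of 1.00. Of the 59 named probes, 0 and 1 had an unadjusted p below 0.05. For cyp1a3 the interactions were 0.095 and -0.087.

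Of the 72 tests of 6 gene lists in 12 comparisons, 0 passed by limma's camera, with a preset or an estimated correlation, and 0 by fry in either direction or mixed. At an unadjusted camera p below 0.05 there were 4. The smallest adjusted p was 0.133, for proteolysis and autophagy in LDL against F without 3AB (median log2 difference -0.12), and with only probes well above background on all 22 arrays this list passed at 0.0158, but not with an estimated correlation, at 0.263. Under the same filter the nuclear receptors, of which 3 genes were left, RARa among them, passed in LDL against F with 3AB, at 0.00133, or 0.0260 with an estimated correlation. That is fewer than the minimum of 5 genes set for the lists. The rise of RARa in this comparison also rested on 1 array: it turned to -0.14 without male 2 of LDL with 3AB. In the averaged comparison of 3AB, the camera adjusted p was 0.772 for oxidative stress and antioxidant genes (5 genes, median log2 difference -0.0048), 0.597 for the list fixed as skeletal muscle contractile genes (5 genes, -0.075), of which 4 measured members are myogenic regulators (myod1, mrf4, myf5 and myogenine) and 1 a myosin light chain (fast_mlc3), 0.759 for nuclear receptors (6 genes, -0.014), 0.759 for muscle and tendon development (9 genes, -0.038), 0.759 for proteolysis and autophagy (10 genes, 0.034) and 0.597 for glucose and lipid metabolism (13 genes, 0.028). No member passed over all probes tested. Adjusted over the list alone, 1 member of the glucose and lipid group passed and 0 members of the other lists. Mean and median had the same sign in each of these 6 lists. The members with the smallest p were SOD1, GPX1, SOD2 and catalase among oxidative stress genes, myod1, mrf4, fast_mlc3 and myogenine in the list of myogenic regulators and fast_mlc3, PPARg, PPARa, PPARb and RARa among nuclear receptors, Pax7, myod1, mrf4 and Wnt4b in muscle and tendon development, LC3B, calpain_1, atg12l and cathepsine in proteolysis and autophagy, and Glut2, glucose-6-phosphatase, phosphoenolpyruvate and ATP-citrate in glucose and lipid metabolism. Their log2 differences lay between -0.36 for PPARg and 0.39 for glucose-6-phosphatase. Single arrays decided the direction of myogenine, -0.043 and 0.021 without male 2 of EY with 3AB, and of RARa, 0.27 and -0.029 without male 2 of LDL with 3AB.

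Many probes differed between the arrays of different males. With group in the fit, 10059 of the 52080 probes (19.3%) were called between the 4 males, with a median range of 0.58 on the log2 scale between the highest and the lowest male, and 1360 probes had a range above 1. Slides 1 and 3 held arrays of all 4 males and slide 2 those of 3. With slide as a block, 8933 probes were called, 7632 of them among the 10059. With array brightness as a covariate, 1525 were called, 1352 of them among the 10059, and with slide and brightness 226. With normexp background 25745 were called. The count depended on the arrays of male 3: it was 5003 without that of F without 3AB, 4794 without that of F with 3AB, 5245 without that of LDL without 3AB, 4585 without that of EY without 3AB and 12638 without that of LDL with 3AB. Of the 59 named probes, 16 passed. The 10 with the smallest p were skelemin, mrf4, fast_mlc3, MSX1, the second scleraxis probe, glucose transporter 1, ATP-citrate, Fast_myosin, fast_mlc1 and MSS1, with adjusted p-values from 0.00423 to 0.0233. The other scleraxis probe did not pass, with a range of 0.23 and an adjusted p of 0.369 by the moderated F-test. Skelemin had the smallest, with deviations from the mean of the males of -0.41, -0.17, 0.33 and 0.26 for males 1 to 4. Its adjusted p was 0.00901 with slide and 0.0463 with brightness in the fit, and it was the 1 named gene that passed with brightness. With brightness the ranges of the second scleraxis probe and glucose transporter 1 were 0.37 and 0.35, against 0.36 and 0.34 without it. Those of mrf4, fast_mlc3, MSX1, ATP-citrate, Fast_myosin, fast_mlc1 and MSS1 fell from 0.58, 0.51, 0.56, 0.83, 0.68, 0.55 and 0.51 to 0.36, 0.16, 0.29, 0.59, 0.14, 0.092 and 0.33. ATP-citrate did not pass with slide in the fit, at 0.0531, where its range between males was 0.80 against 0.83 without slide. Fast_myosin, fast_mlc1 and MSS1 no longer passed without male 3 of F with 3AB (adjusted p from 0.0545 to 0.0652), of LDL without 3AB (0.0563 to 0.0679) or of EY without 3AB (0.0643 to 0.0657). With quantile normalisation, fast_mlc3, Fast_myosin, fast_mlc1 and MSS1 did not pass, at adjusted p-values of 0.592, 0.651, 0.871 and 0.0522, and their ranges fell from 0.51, 0.68, 0.55 and 0.51 to 0.11, 0.10, 0.054 and 0.34. Male was confounded with everything else done once per replicate.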

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

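Tests chosen after the result was seen were those of brightness for the probes called for 3AB and for the males. So were those of slide for the lost probe and for the males, and the exchange of labels within males. The others in this part were chosen before, but the lost probe was itself chosen after its values were seen. Its test of weaker detection is thus not independent of that choice.

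Within groups of 4 arrays, 205 sets of values were searched for an array far from the other 3, and 12 were found (5.85%), where chance gives about 1 in 20. Of these, 3 fell on male 3 of EY without 3AB. Its log2 75th percentile was 9.01 (the others 9.94 to 10.09), and relative to it fast_mlc3 stood at 8.57 (7.93 to 7.96) and Fast_myosin at 8.53 (7.76 to 7.83). On male 3 of F without 3AB, PPARg was -7.38 (-6.36 to -6.17). On male 3 of LDL with 3AB, fbx32 was -6.81 (-5.28 to -4.97) and Wnt4b -2.71 (-1.93 to -1.89). On male 1, mrf4 was -0.88 in F with 3AB (-1.39 to -1.35) and -0.95 in LDL with 3AB (-1.45 to -1.39), phosphoenolpyruvate was 3.28 in LDL with 3AB (3.16 to 3.18), PPARb was -2.98 in F without 3AB (-2.67 to -2.62) and elov12 was 0.89 in LDL without 3AB (1.41 to 1.51). On male 2 of LDL with 3AB, RARa was -0.37 (-3.95 to -3.88). The number found is close to the number chance gives, and no explanation of single values was tested.

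The first pattern is the set of 361 probes called for 3AB averaged over sperm. The arrays are paired by male, and labels were exchanged within the 10 pairs, which allows 1024 ways. Chance is argued against but not excluded: 1 of 100 such splits, the real one, called as many, and the highest of the others called 16. A share of 1 in 100 is the smallest that these splits can give. Of 100 draws of labels within each kind of sperm that ignore the pairs, 1 called as many and the highest other called 3. For F and LDL alone, the splits that part every pair, as the real one does, are 8, too few for a share under 0.05: the real split called 12 probes in F and 19 in LDL, and the highest other of these 0 in both. Among all 35 splits, 1 called as many in F and the highest other 3, and 1 in LDL and the highest other 0. The remaining splits put both arrays of some males on the same side, so that differences between males enter them.

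Slide as the whole cause of the 361 probes is argued against by probes called from the other slides, of which at least 98.4% had the same direction within the slide left out. Median differences within slides 1, 2 and 3 were 0.95, 1.07 and 0.97, against 1.04, 1.18 and 1.27 on the other slides. Array brightness is argued against as the whole cause by its direction: with 3AB the mean log2 brightness changed by -0.035 in F and -0.33 in LDL but by 0.39 in EY, and of the probes called from F and LDL 98.3% had the same direction in EY. A response to the treatment with 3AB had its needed values: of probes called from any pair of kinds of sperm, at least 98.3% had the same direction in the kind left out (174 of 177 in EY, 66 of 66 in F and 57 of 57 in LDL). Anything else done to all eggs with 3AB and to none without stays open, as the design does not part it from the drug. A candidate explanation, as a hypothesis found and tested on the same arrays, is an effect of the treatment on the larvae, with the 98.3% as its least favourable value.

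The second pattern is the probe CUST_11300_PI425536763, lost with 3AB. Within every slide and kind of sperm that held both treatments its signal was at least 124-fold higher without 3AB. In F and EY this cannot test slide. The probe was chosen for being well above background on every untreated array and on no array of F or EY with 3AB. LDL with 3AB was not part of that choice. There, on slide 2, the 124-fold difference argues against slide, but it rests on 1 array of each treatment. A generally weaker detection on the arrays with 3AB is argued against by the other probes. Of 42499 probes well above background on every untreated array, 1 was missing on at least 9 of the 10 arrays with 3AB, or 0.00235%. That 1 is this probe, which was chosen by a similar rule. Of 43413 on every array with 3AB, 0 were missing on at least 11 of the 12 untreated. What the probe measures is not named in the files. A fall of a transcript in the larvae, and a sequence that came with the handling of the untreated eggs alone, stay open and were not tested.

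The third pattern is the 10059 probes that differed between males. Chance is argued against but not excluded: 1 of 100 draws of males within each group, the real one, called as many and the highest other called 4861. With brightness as a covariate, 1 of 100 called 1525 and the highest other 11. A share of 1 in 100 is the smallest that these draws can give. Draws that called up to 4861 probes without brightness in the fit point to a structure of the arrays besides the labels, and brightness may follow it. Slide is argued against as the whole cause, as 8933 probes were called with it as a block, 7632 of them among the 10059. Brightness and male cannot be told apart for most of these probes: 1525 were called with brightness as a covariate, but brightness itself differed between males, and a real difference in RNA between males could set it. Differences between the sires, and between the handling of replicates, stay open.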

How the results depend on the processing

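The fits with array brightness as a covariate and with male and slide together were chosen after the result was seen. Of 138 counts under other settings, 109 stayed within 1.5 times and 29 moved, and of 140 counts without 1 array, 116 stayed and 24 moved. A count of 0 that remained 0 was scored as stayed. The comparisons between kinds of sperm, the interactions and the gene lists had 0 in the main fit and make up much of these totals. The totals therefore overstate how steady the counts for 3AB and between males were. Unless given, the cause was not tested.

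The replicate block (male) called 21 probes for 3AB in F, 38 in LDL, 15 in EY and 799 averaged and turned cyp1a3 averaged to -0.011. Slide as a block called 6, 1, 4 and 126, with cyp1a3 at -0.039 in F and -0.017 averaged. The slides hold the groups unevenly, and the median standard error of the averaged comparison rose from 0.113 to 0.132. Male and slide together called 1 in F, a fall, 1 in LDL, a rise where 15 of 19 had fallen, 12 in EY, 5 higher and 7 lower, 185 averaged, 1 for LDL against F without 3AB, and 1 gene list (nuclear receptors, EY against F with 3AB, adjusted p = 0.0217, or 0.199 with an estimated correlation). CUST_6770_PI425536763 no longer passed averaged there (2.27, adjusted p = 0.0575). In LDL CUST_11300_PI425536763 no longer passed either: its log2 difference was -8.46 (SE 0.66, adjusted p = 6.38e-06), -8.14 (SE 0.91, 0.00498) with slide and -8.15 (SE 1.03, 0.0529) with male and slide, so the call ended by the larger standard error more than by the difference. Brightness as a covariate called 575 averaged, all 361 among them, and 1525 between males.

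With normexp background the counts were 7 in F, 9 in LDL, 9 in EY (1 higher and 8 lower, against 4 and 5), 214 averaged and 25745 between males, and 4 lists passed: the list fixed as skeletal muscle contractile genes, here 4 myogenic regulators and fast_mlc3, for 3AB in LDL (adjusted p = 0.0386), proteolysis and autophagy for EY against F without 3AB (0.00758), and oxidative stress and glucose and lipid metabolism for LDL against EY without 3AB (0.0247 each). None of the 4 passed with an estimated correlation, at 0.116, 0.136, 0.230 and 0.0777. The median of all probes went from 0.029 to 0.10 for 3AB in LDL, from -0.0079 to -0.11 for 3AB in EY, from -0.014 to -0.10 for EY against F and from 0.016 to 0.13 for LDL against EY with 3AB, and from -0.0064 to -0.11 in the interaction of EY. PPARg turned to 0.082 for 3AB in LDL, -0.068 for LDL against F without 3AB, -0.20 for EY against F with 3AB, 0.28 for LDL against EY with 3AB and 0.15 in the interaction of LDL. RARb turned to -0.17 for 3AB in EY, -0.019 for LDL against EY without 3AB and -0.074 in the interaction of EY. The probe for cyp1a3 turned to 0.0079 for EY against F without 3AB and -0.030 in the interaction of LDL.

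Quantile normalisation called 15 for 3AB in EY, 4 higher and 11 lower, and 1 for LDL against EY with 3AB. No filter called 7 in F and 4 in EY, as more probes were tested. With probes well above background on all 22 arrays, 10 were called in EY, 1 higher and 9 lower, and 3 lists passed: proteolysis and autophagy for LDL (0.0158) and EY (0.0294) against F without 3AB, and nuclear receptors for LDL against F with 3AB (0.00133). Of the nuclear receptors 3 genes were left, RARa among them, fewer than the minimum of 5. With an estimated correlation the first 2 did not pass, at 0.263 and 0.219, and the last did, at 0.0260. The values of the series matrix turned cyp1a3 to 0.00042 for 3AB in EY and 0.015 for LDL against EY without 3AB. They called 19 lower of 21 in LDL and 7 of 10 in EY. Only the groups compared, with fewer arrays to estimate the spread, called 3 in F, 2 in LDL, 2 in EY and 1 for LDL against EY with 3AB; averaged over sperm this is the fit to all arrays, and it does not apply to males.

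Without 1 array, counts ranged from 6 (male 4 of F without 3AB) to 16 (male 1 of F without 3AB) for 3AB in F, from 3 (male 3 of LDL with 3AB) to 19 in LDL, and from 4 (male 3 of EY without 3AB) to 60 (male 2 of EY with 3AB) in EY. They ranged from 0 to 46 for EY against F with 3AB, 0 to 47 for LDL against EY with 3AB and 0 to 26 in the interaction of EY, the highest each without male 2 of EY with 3AB, which left 1 array assumed to vary like the other groups. Between males they ranged from 4585 (without male 3 of EY without 3AB) to 12638 (without male 3 of LDL with 3AB), and averaged over sperm from 254 to 376. RARa ranged from -0.14 (without male 2 of LDL with 3AB) to 1.05 for LDL against F with 3AB and from -0.029 (without the same array) to 0.37 averaged, and myogenine averaged from -0.11 to 0.021 (without male 2 of EY with 3AB). The probe for cyp1a3 ranged from -0.088 to 0.11 for 3AB in F, -0.022 to 0.053 averaged, -0.13 to 0.066 for EY against F without 3AB, -0.15 to 0.031 for LDL against EY without 3AB, -0.095 to 0.12 for LDL against F with 3AB, -0.0064 to 0.22 in the interaction of LDL and -0.19 to 0.010 in that of EY, so it has no direction in these.

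Named genes kept direction and side of the threshold in 835 of 866 settings, the 4 shown probes in 39 of 40 in the averaged comparison and the genes named for males in 74 of 90, 16 no longer passing. The 835 do not show steady effects: no named gene passed a comparison in the main fit, so keeping its side means that it again did not pass. The fits added after the data were seen were not scored for named genes in the comparisons. Within kinds of sperm, slide as a block ended the call of CUST_9458_PI425536763 in LDL (-3.07, SE 0.50, adjusted p = 0.0207, to -2.70, SE 0.63, 0.744) and those of CUST_4911_PI425536763 in F (1.75, SE 0.28, 0.0369, to 1.65, SE 0.32, 0.262) and EY (2.19, SE 0.35, 0.0386, to 2.30, SE 0.37, 0.0979). The last passed with male and slide together (2.45, 0.0371). Signal over background limits the dim probes: of 52080 tested, 41944 were well above background on all 22 arrays.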

Other observations

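The tests of the label of male 1 of F without 3AB and of a curved effect of brightness were chosen after the result was seen; the test of brightness as a straight line for males 1 and 3 against males 2 and 4, and the splits, were chosen before.

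Arrays were placed between the untreated mean (0) and the 3AB mean (1) by the probes called without them. Male 1 of F without 3AB had a median position of 0.345, where the other untreated arrays lay between -0.04 and 0.19 and those with 3AB between 0.63 and 0.97. This gap depends on the median. By a second summary over the same probes the array lay at 0.368, and males 1 and 2 of EY with 3AB lay at 0.484 and 0.360. A wrong treatment label is argued against, because this position is nearer to the untreated mean, 39.1% of the probes were nearer to the 3AB mean, and the probe lost with 3AB was well above background on it. A mixture of samples was not tested. Without this array, 376 probes were called averaged over sperm and 16 for 3AB in F.

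Where the real comparison called no probe, every split calls at least as many, so that the share of splits says nothing of chance. In LDL against F without 3AB, 35 of 35 splits called at least the real 0 and the highest other called 75. In EY against F without 3AB it was 35 of 35, with 47 as the highest, in LDL against EY without 3AB 35 of 35, with 31, and in LDL against F with 3AB 35 of 35, with 163. Each of these highest splits put males 1 and 3 against males 2 and 4, and so points to a structure of the samples. The 8 splits that part every pair called 0 in each of the 4 comparisons; the others join arrays of the same male. For the interaction of LDL against F, 100 of 100 draws called at least the real 0 and the highest other called 2534.

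The hypothesis that array brightness explains males 1 and 3 against males 2 and 4 was tested over all groups. Of 1595 probes called between these pairs of males, 94.7% were still called with brightness as a covariate. This decides nothing, because the mean log2 brightness of the pairs differed by only -0.082, males 1 and 3 being the brightest and the dimmest. With brightness and its square as covariates 56.1% were still called, all 1595 kept their direction, and their median absolute log2 difference went from 0.44 to 0.42 and their median standard error from 0.0903 to 0.0916. A curved effect of brightness and a difference between these males cannot be told apart for the probes no longer called. With slide as a block 761 probes were called. For males 1 and 2 against 3 and 4 the counts were 5376 and, with brightness, 17, and for males 1 and 4 against 2 and 3 they were 3696 and 0. A difference between the sires, or between replicates handled together, may lie behind these calls, and the design does not part these.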
